A study of Arabidopsis thaliana with 6 samples.

How the data were processed

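Root tips of Arabidopsis thaliana were compared between a quadruple mutant in class III homeodomain-leucine zipper (HD-ZIP III) genes and its Col er-2 wild type. The mutant carries athb8-11 in ATHB8, cna-2 in CNA, phb-13 in PHB and phv-6 in PHV, which leaves REV as the remaining member of the family. Per the labels' protocols, tips of about 0.5 mm were cut by hand from seedlings 4 days after germination, and about 200 tips made up a replicate. The input for each Affymetrix ATH1 array was 250 ng of total RNA. Each genotype had 3 arrays, which the series' design text calls biological replicates, and groups and replicate numbers were taken from the labels.

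The deposited table gave 1 log2 signal per probe set and array, for 22810 probe sets and 6 arrays. Affymetrix Expression Console, RMA and limma are named in the submitters' processing notes, without version or role. That the deposited values are RMA log2 signals, which are background corrected, quantile normalized and summarised over the probes of a set, follows from those names and from the range of the values. Quantile normalization forces the arrays to nearly one distribution, so a shift shared by most genes would not be visible, and RMA compresses differences of dim probe sets. The table held no detection calls, so a low signal was not read as absence of a transcript. No scan date or other batch was given by the labels.

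From these values, 64 control probe sets were left out and the other 22746 were tested as mutant minus wild type with limma 3.58.1 in R 4.3.3, using lmFit and eBayes without trend or robust options. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05. Intervals given below are 95% confidence intervals from that fit. The number of arrays, 3 per genotype, limits the precision, and the median standard error of a log2 difference was 0.10.

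Gene names came from a probe table that lists only part of the array, with symbols updated by locus through the TAIR10.1 gene table. Of the probe sets tested, 13513 named 1 gene, 503 named several and 8730 were not listed, so they are unnamed here and given by probe set. A locus in the TAIR10.1 table was found for 13484 of the 13513. Where a gene had several probe sets, that with the highest mean over all arrays stood for it, which left 13355 genes. The files name no genome build, and no coordinates are given.

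Fixed before the data were examined were the tests, the alternatives, 18 gene lists and the rule for naming genes. The lists held 293 entries at 281 loci, of which 46 entries at 40 loci could be named on the array. For 5 of these the list's symbol was not borne out by the TAIR10.1 table, and they are given by locus. The rule named the mutated genes, REV and ER, the called genes with the largest changes, and up to 2 members of each list by smallest p where none was called. Because fewer than 5 named genes were called, it turned to the 10 named genes with the smallest p. Called probe sets without a name, and list members beyond the first 2, fall outside that rule and were chosen after their values were seen.

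Each list was counted over all probe sets and adjusted over the list alone. The latter adjusts only over the few named members of a list and not over the 18 lists, so it is lenient. The 4 lists with 4 or more named members were tested for a shift against all other genes with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation as an alternative. The fry test was run beside it, which tests a list against no change and not against other genes. Array medians and the 3' minus 5' signals of control transcripts were compared by exact two-sided permutation tests, for which 3 against 3 arrays give 20 label orders and a smallest p of 0.1. Called genes were compared with all others for lying within 200 loci of a mutated locus by Fisher's exact test. The same test over genes with an unadjusted p under 0.01 was added after the data were seen. Alternatives were each array left out, the replicate number as a block, a filter on dim probe sets, other prior variances, median centring, quantile normalization repeated, array weights, an equal-variance test per probe set and other thresholds.

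The fit was tested on simulated data made from the spread of these arrays over 22746 probe sets. Each simulation changed 100 probe sets by log2 1 and 100 by log2 0.5. Of changes of log2 1, 82.8% were recovered, and of changes of log2 0.5, 34.2%. The Benjamini-Hochberg cutoff is looser when more probe sets change. These shares therefore cannot be carried over to the real arrays, where only 6 probe sets were called. Among the simulated calls 4.49% were false, and with no change there were 0 calls. The list of auxin genes, shifted by log2 0.5, had a camera p under 0.05, not adjusted over lists, in 20 of 20 simulations. The simulated probe sets were drawn independently of each other. False calls and list shifts among correlated genes, as on real arrays, were therefore not tested.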

Results

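Transcript levels were measured on 6 ATH1 arrays, 3 from root tips of the quadruple HD-ZIP III mutant and 3 from Col er-2 root tips. HD-ZIP III proteins are transcription factors that pattern vascular tissue, where high activity in the root stele goes with metaxylem and low activity with protoxylem. The arrays had median log2 signals between 5.56 and 5.59, and any pair of arrays correlated across probe sets at 0.989 to 0.996, with 0 identical pairs. A first principal component held 41.4% of the variance and did not separate the genotypes. Wild type replicate 1 lay at its end, at -28.1, and mutant replicate 1 came next, at -11.4. The other arrays lay from -0.96 to 18.5. The second component held 24.1%, and on it the mutant arrays lay between -15.0 and -4.34 and the wild type arrays between 1.48 and 21.0. The array medians were higher in the mutant, 5.59 against 5.56, and a second set of GAPDH controls had a smaller 3' minus 5' difference, 0.07 against 0.17. Both had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow, and a Benjamini-Hochberg adjusted p of 0.35 over 7 relations. The question was which transcripts of the root tip depend on ATHB8, CNA, PHB and PHV.

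PHV, a mutated gene and the only family member named here, had a log2 signal of 4.74 ± 0.16 (SD, n = 3) in the mutant and 5.66 ± 0.15 in the wild type. Its signal was lower on each mutant array than on any wild type array. The difference of -0.92 (95% confidence interval -1.18 to -0.65) had an adjusted p of 0.0639 with limma and Benjamini-Hochberg over all probe sets, and adjusted over the list alone, a list of 1 gene, p was 4.21e-05. Where this probe set lies relative to the lesion is not known from the labels, so its level is a limited check of the genotype. ATHB8, CNA, PHB, REV and ER could not be matched to a probe set by name, so no value is given for them. Any probe set of theirs was among those tested without a name. Whether an unnamed called probe set, given below, measures any of these genes is not known here.

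A single probe set stood far from all others. The signal of 253952_at was 5.33 ± 0.16 (SD, n = 3) in the mutant and 10.72 ± 0.14 in the wild type, which is 41.9-fold lower in RMA signal, with a limma Benjamini-Hochberg adjusted p of 7.08e-07. The other called probe set that fell, 265060_at, changed by -1.31 on the log2 scale (adjusted p = 0.00525). The mutant signals of both, and that of PHV, lay below the array medians and have no detection call, so their folds are those of the signals and not of the transcripts. Among the named genes, AT3G48970, which encodes a protein with a heavy-metal-associated domain, rose from 5.48 ± 0.15 to 6.62 ± 0.07, a log2 difference of 1.14. AT1G55210, which encodes a dirigent-like protein of a family that guides phenoxy radical coupling, rose from 8.77 ± 0.05 to 9.53 ± 0.06, a log2 difference of 0.76. Their limma Benjamini-Hochberg adjusted p were 0.0141 and 0.0328. The unnamed probe sets 249115_at and 265656_at rose by 1.27 and 0.96 (adjusted p = 0.0263 and 0.0110).

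**Figure D1:**
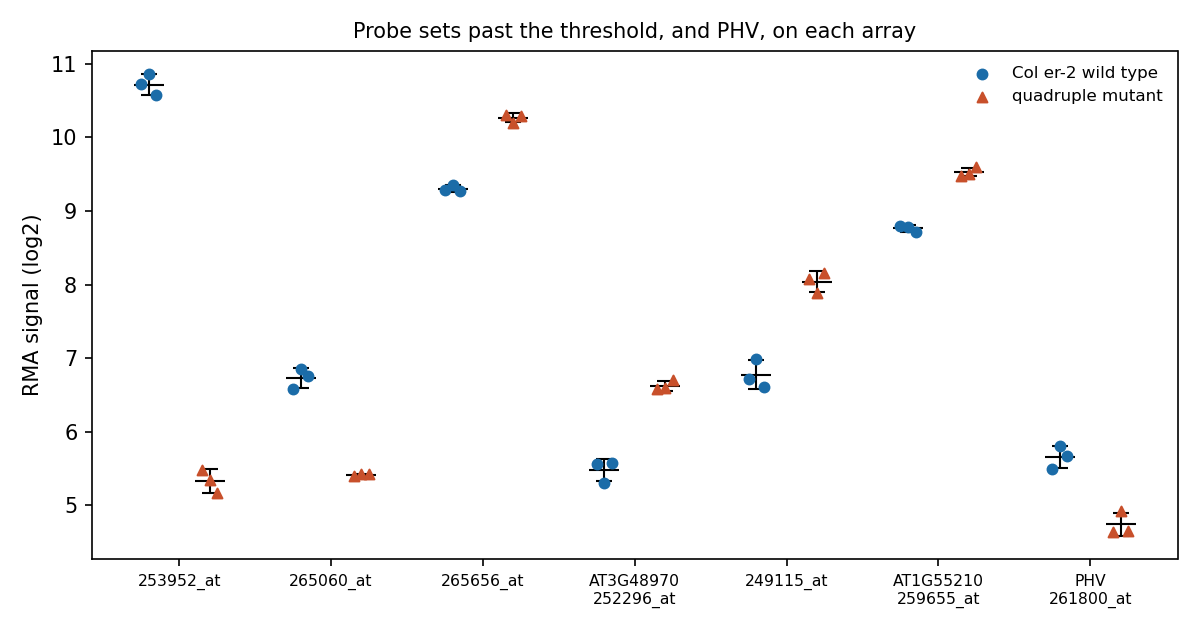
RMA log2 signal (vertical axis) on each array for the 6 called probe sets and for PHV, in wild type (circles) and quadruple mutant (triangles), with the mean and SD of 3 arrays in black. For 253952_at the mutant arrays lie between 5.16 and 5.48 and the wild type arrays between 10.57 and 10.86.

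In all, 6 of 22746 probe sets passed limma's test at a Benjamini-Hochberg adjusted p under 0.05, 4 higher and 2 lower in the mutant. At an unadjusted p under 0.05 there were 1698, where 1137.3 would be expected by chance. The groups did not overlap in 2985 probe sets, or 13.1%, where chance gives 10%. Without mutant replicate 1, 2 or 3 the count was 1 each time, that of 253952_at, and it was 5, 3 and 8 without wild type replicate 1, 2 and 3. Of those 5, 3 and 8, only 4, 3 and 4 were among the 6 called with all arrays. An equal-variance test per probe set with Benjamini-Hochberg adjustment called 1. Other settings called more, from 11 with repeated quantile normalization to 109 with the replicate block, and are given below.

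Of the next named genes by p, none passed the threshold in the fit used here, and what alternatives gave follows their values. AT1G47410 differed by 0.92 and AT5G50010, which encodes a bHLH protein of the SAC51 family, by 0.63, both with a limma Benjamini-Hochberg adjusted p of 0.0639. The mean signals of AT5G50010, 5.44 in the mutant and 4.82 in the wild type, lay below the array medians. AT2G34060, a peroxidase gene, differed by 0.96 (adjusted p = 0.0713). EXPB1, a beta-expansin that acts in wall loosening, differed by -0.81 and AT3G50640 by -0.74, both with an adjusted p of 0.0739. AT4G38410, of the dehydrin family, differed by 1.15 (adjusted p = 0.0937), and CP1, a cysteine proteinase gene, by -0.79 (adjusted p = 0.101). All of these passed with the replicate number as a block (limma Benjamini-Hochberg adjusted p = 0.0110 to 0.0360). All but AT5G50010 passed with the trend and robust options, and all but AT3G50640 with array weights. None passed with any array left out or with the equal-variance test.

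Among reported HD-ZIP III targets, 4 of 16 were named on the array, and 0 of the 4 passed limma's Benjamini-Hochberg threshold over all probe sets, with 1 at an unadjusted p under 0.05. BBM, an AP2-domain factor of the PLETHORA family that maintains root stem cells, had a mean signal of 6.65 ± 0.10 (SD, n = 3) in the mutant and 6.23 ± 0.23 in the wild type. Its difference of 0.42 had an adjusted p of 0.463 over all probe sets and 0.0368 adjusted over the list alone, the only such call in this list. IAA20 and IAA30, auxin response repressors that lack the degron, differed by -0.0038 (95% confidence interval -0.19 to 0.18) and -0.02 (-0.22 to 0.19). Both had mean signals below the array medians and no detection call, so these intervals are those of the signals and not of the transcripts. HAT2, a class II HD-ZIP gene, differed by -0.02. The median of the list was -0.01 and its mean 0.10, and camera gave the direction as up with an adjusted p of 0.384.

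None of the few xylem and other vascular genes named here passed, which were 2 of 33 entries of the xylem list, 3 of 13 early vascular regulators and 4 of 21 phloem and procambium genes. IRX15 and IRX10, which act in xylan synthesis of secondary walls, differed by 0.22 and 0.13 (adjusted p = 0.766 and 0.873 with limma and Benjamini-Hochberg). Of the early vascular regulators, LHW, a bHLH factor that promotes vascular cell division, differed by 0.22, AT2G28510 by 0.28 and AT5G15950 by 0.18, with 0 of 3 past the threshold and 0 at an unadjusted p under 0.05. AT5G15950 had the widest interval of these, -1.03 to 1.40, and its place in the list is in doubt, since the symbol it was listed under is not borne out by the TAIR10.1 table. A single array moved several of the values, to 0.05 for LHW without wild type replicate 1, 0.13 for AT2G28510 without wild type replicate 3, and 0.13 for IRX15 and 0.04 for IRX10 without mutant replicate 2. In the phloem and procambium list OPS, a regulator of phloem initiation, differed by 0.19, AT5G02460 by 0.07, and the peptide genes CLE41 and CLE44 by 0.06 and 0.02. None of those 4 passed, none had an unadjusted p under 0.05, and the list had a camera adjusted p of 0.384.

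In the mitotic and S-phase list, the 3 members named of 31 had higher mean signals in the mutant, and 0 of 3 passed limma's Benjamini-Hochberg threshold over all probe sets, with 3 at an unadjusted p under 0.05. AUR2 and AUR1, Aurora kinases of mitosis, differed by 0.28 and 0.20, and MCM7, a subunit of the replicative helicase, by 0.26. Their adjusted p over all probe sets were 0.528, 0.649 and 0.626 with limma and Benjamini-Hochberg. Adjusted over these 3 members alone, and not over the 18 lists, each was at 0.0418. In the stem cell niche list, with 3 of 11 named, AGL42 and CLE40 differed by 0.06 and 0.04. BBM, the same probe set as given above, had a limma Benjamini-Hochberg adjusted p of 0.0276 over this list alone.

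Auxin genes, with 8 of 35 named, gave 0 of 8 past the limma Benjamini-Hochberg threshold and 1 at an unadjusted p under 0.05. That gene was GH3.5, which encodes an enzyme that conjugates auxin to amino acids, at 5.79 ± 0.10 (SD, n = 3) in the mutant and 5.33 ± 0.05 in the wild type. Its difference of 0.46 had an adjusted p of 0.196 over all probe sets and 0.00419 adjusted over the list alone. IAA29 differed by 0.13, LBD16 by 0.09, GH3.3 by 0.06, LBD29 by 0.04 and GH3.1 by 0.02. With IAA20 and IAA30, given above, 6 members were higher and 2 lower, or 5 and 3 after median centring or repeated quantile normalization. The list's shift had a camera adjusted p of 0.271, and an adjusted p of 0.427 with an estimated correlation. The fry test, which sets the list against no change and not against other genes, gave a Benjamini-Hochberg adjusted p of 0.194 for movement in one direction and 0.00676 for movement in either.

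Of the 33 genes of the cytokinin list, the type-A response regulators ARR15 and ARR16 differed by 0.29 and 0.04 (limma Benjamini-Hochberg adjusted p = 0.653 and 0.964), with 1 of 2 at an unadjusted p under 0.05. COR47 and COR15A, 2 of 14 of the abscisic acid list, differed by 0.13 and 0.06. KANADI genes and genes of gibberellin and brassinosteroid metabolism had 0 members named here.

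Markers of other root tissues were read for the makeup of the dissected pieces, with 3 of 16 ground tissue genes named, 2 of 14 of epidermis and root hair, 2 of 7 of root cap, 4 of 7 of lateral root and pericycle, 2 of 9 of photosynthesis and 1 of 14 of handling. In the ground tissue list AT1G62500, a gene used as a cortex marker, was at 8.10 ± 0.23 (SD, n = 3) in the mutant and 7.53 ± 0.19 in the wild type. Its difference of 0.57 had a limma Benjamini-Hochberg adjusted p of 0.369 over all probe sets and 0.0109 adjusted over the list alone, 1 of 3 members, while SNE and JKD differed by 0.31 and -0.14. EXPA7 and EXPA18, expansin genes of root hair cells, differed by -0.17 and -0.11. The root cap genes AT1G65570 and ACR4 differed by 0.43 and 0.08, and AT1G65570 by 0.18 without wild type replicate 2 and 0.27 without mutant replicate 3. Of the lateral root and pericycle list, ACR4, LBD16, LBD29 and PUCHI were higher by 0.04 to 0.09, with a camera adjusted p of 0.384. RCA and LHCB4.1, genes of photosynthesis in green tissue, differed by -0.33 and -0.22, and ZAT10, a zinc-finger gene that responds to handling, by -0.09. Without wild type replicate 3 the differences were -0.12 for RCA, -0.08 for LHCB4.1 and -0.66 for ZAT10, and without wild type replicate 1 that of ZAT10 was 0.24. Over these 5 lists and the handling gene, 0 members passed over all probe sets and 1, AT1G62500, had an unadjusted p under 0.05.

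**Figure D2:**
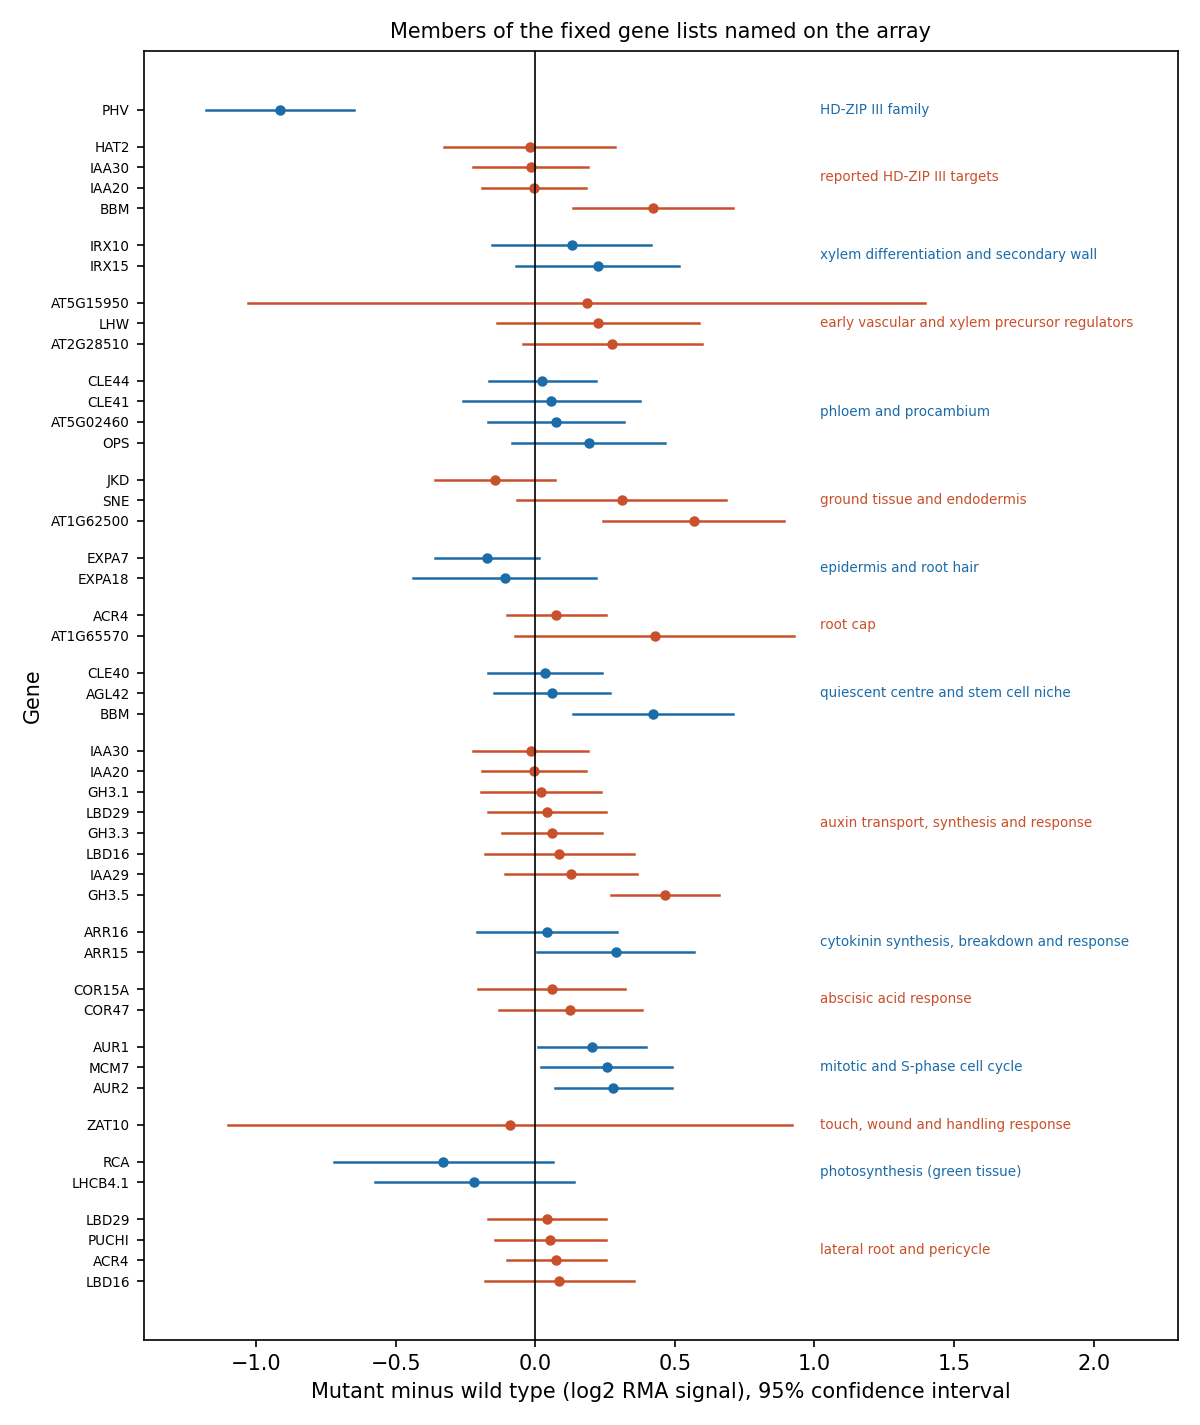
Log2 difference in RMA signal, mutant minus wild type (horizontal axis), of each gene of the fixed lists that was named on the array, with its 95% confidence interval, grouped by list in alternating colours. PHV lies at -0.92, and the intervals of BBM, GH3.5, AT1G62500, ARR15, AUR1, AUR2 and MCM7 lie above 0.

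Called genes were also placed along the chromosomes, since a segment of another background can travel with a mutant allele. Of the genes past the limma Benjamini-Hochberg threshold with a known place, 0 of 2 lay within 200 loci of a mutated locus (Fisher's exact test, two-sided p = 1). The 4 unnamed probe sets have no place here. AT2G34060, given above among the genes that did not pass, lies by its locus number within 200 loci of PHB (AT2G34710). Whether its difference comes from such a segment was not tested.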

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

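Of 555 recomputed values of named genes and called probe sets, 489 kept their direction and side of the threshold, 27 were no longer past it, 26 were newly past it and 13, none of them past it in either setting, turned sign. The probe set 253952_at was called in all 14 alternatives that refit it, and the 6 called probe sets were all called again with the dim probe sets left out, median centring and the settings with more calls named next. Against 6 calls, 4 higher and 2 lower, the replicate block gave 109 (33 higher, 76 lower), eBayes with trend 14 (8 lower), trend with robust 27 (12 higher, 15 lower), quantile normalization repeated 11 (6 higher, 5 lower) and array weights 22 (11 higher, 11 lower). The equal-variance test per probe set gave 1 (0 higher, 1 lower). The cause of these moves was not tested. With the replicate block, the numbers alone do not establish pairs. Same-numbered arrays correlated in their deviations at 0.504, 0.07 and 0.176, and mutant replicate 2 correlated best with wild type replicate 3 (0.317). The 0.504, of replicate 1, was the highest of any mutant and wild type pair. The first principal component also put replicate 1 of both genotypes furthest to the same side. A factor shared by replicate 1 of both genotypes is therefore not excluded, and it was not tested. By construction the thresholds moved the counts, to 2 (0 higher) at an adjusted p under 0.01, to 19 (10 higher, 9 lower) under 0.1, and to 2 higher at 2-fold or more. Leaving out 1 array gave 1 to 8 calls, 0 to 2 higher and 1 to 6 lower, with 1 without each of the mutant replicates 1, 2 and 3. Genes that turned sign with 1 array left out ran from -0.073 to 0.031 (IAA30), -0.0090 to 0.16 (AT5G02460), -0.27 to 0.011 (EXPA18), -0.051 to 0.11 (ARR16), -0.057 to 0.15 (COR15A), -0.66 to 0.24 (ZAT10) and -0.027 to 0.18 (LBD16), and COR15A was at -0.031 with array weights; the cause was not tested. A single left-out array moved 21 of the 41 named differences by over 1.5 times, and 0 of the 6 called ones. Over all alternatives OPS ran from 0.11 to 0.32, SNE from 0.18 to 0.47 and COR47 from 0.04 to 0.24. IAA29 ran from 0.07 to 0.21 and ARR15 from 0.19 to 0.38. PHV passed with the replicate block at -0.92, with trend and robust at -0.92, with repeated quantile normalization at -0.91 and with array weights at -0.995, so that the HD-ZIP III list had 1 member past the threshold in each, and its adjusted p ran from 0.0102 to 0.528 over 13 alternatives. The window of 500 loci held 1 called gene, where 200 loci held 0 (Fisher's exact test, two-sided p = 0.207). No list shift passed in any alternative of camera, with adjusted p from 0.147 to 0.680, and fry, which tests against no change, gave adjusted p of 0.194 to 0.219 in one direction. With dim probe sets left out no list kept 4 members, so that shift was not run. Depth is not defined for arrays, and low signal limits the 13 of 40 named list members under the 35th percentile of all probe sets, a bound set after values were seen: CLE40, ARR16, PUCHI, LBD29, GH3.3, COR15A, EXPA18, AT5G02460, AGL42, IRX15, IAA29, CLE44 and EXPA7.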

Other observations

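Chosen only after values were seen were the genes singled out here, the grouping of genes by symbol, the added lists of cell division genes and expansins, and the tests of position over genes with an unadjusted p under 0.01, of cell share and of piece length, as well as the tests of the called probe sets and of single arrays for the SPIRAL1-LIKE genes. The splits for cell division and for families, and the single-array test for cell division, were written before their results were seen.

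Several genes with large differences did not pass the threshold. The acid phosphatase family genes AT5G44020 and AT1G04040 differed by -1.31 and -0.94, the peroxidase gene AT2G18980 by -0.86 and the lectin gene AT5G35940 by -0.90 (limma Benjamini-Hochberg adjusted p = 0.270, 0.196, 0.150 and 0.126). EXLA2, an expansin-like gene, differed by -0.62 and the beta-tubulin gene TUB5 by -0.54 (adjusted p = 0.299 and 0.281). The receptor kinase genes PXL1 (AT1G08590) and PXL2 (AT4G28650), relatives of the vascular receptor PXY, differed by -0.51 and -0.54 (adjusted p = 0.165 and 0.258). IAA18, an auxin response repressor, differed by 0.44 and AT5G66780 by 1.18 (adjusted p = 0.306 and 0.273). The mean signals of IAA18, 4.94 in the mutant and 4.50 in the wild type, lay below the array medians. AT5G66780 was lowest on replicate 1 of each genotype, at 6.21 in the mutant and 5.26 in the wild type. Of the XTH genes, which remodel xyloglucan in the wall, 8 of 10 were lower, or 7 of 10 after repeated quantile normalization, among them XTH16, XTH18 and XTH19 by -0.90, -0.89 and -0.40. The other lower members, XTH20, XTH21, XTH26, XTH32 and XTH33, had mean signals below the array medians. Of these, XTH20 and XTH32 differed by only -0.0097 and -0.0067. As a family the XTH genes had a camera Benjamini-Hochberg adjusted p of 0.0816, which was 0.823 with an estimated correlation and 0.0319 with the replicate block. Of the beta-tubulin genes 4 of 5 were lower (adjusted p = 0.0883, and 0.823 with an estimated correlation). Families that rose ranked above the XTH and beta-tubulin genes by p. The symbol families MAP and NDH, with 0 of 5 members lower in each, had median differences of 0.15 and 0.21. Each had a camera Benjamini-Hochberg adjusted p of 0.0816, which was 0.823 with an estimated correlation and 0.0798 with the replicate block. Among expansins other than EXPB1 and EXLA2, 9 of 17 were higher and 8 lower, or 8 and 9 after median centring. Their median was 0.02 while camera gave the direction as down, with p of 0.168 and a p of 0.331 with an estimated correlation.

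Some genes set wild type replicate 1 and mutant replicate 1 apart from the other arrays. AT3G15630 had a log2 signal of 9.18 and 8.76 there and 5.69 to 7.07 elsewhere, and AT2G32150 had 7.83 and 7.61 there and 5.10 to 5.57 elsewhere. UGT78D1, a flavonol glycosyltransferase gene, was at 5.28 and 5.23 there and 6.86 to 7.34 elsewhere.

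The 6 called probe sets were the first pattern. The real split of the arrays called 6 and each of the 9 other splits called 0, so 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. A segment of another background around the mutated loci stays open for the called probe sets, since 4 of the 6 have no place here. Among the genes with an unadjusted p under 0.01, 3.94% lay within 200 loci of a mutated locus (odds ratio 0.90, 95% interval 0.42 to 1.70, Fisher's exact test, two-sided p = 0.877), which gives no sign of such a segment in that wider set.

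The higher signals of AUR1, AUR2 and MCM7 were the second. The added list of other cell division genes, corrected after its first result because clone names had matched by mistake, had a median difference of 0.22 over 11 genes (resampling interval 0.10 to 0.27, 10 higher and 1 lower, or 9 and 2 after median centring), with a camera p of 6.92e-05 and a p of 0.0665 with an estimated correlation. Leaving out wild type replicate 1, the array that moved it most, gave 0.14, which argues against that array as the whole source. The real split gave 0.22 in size and the highest other 0.10, so 1 of 10 splits was as large, too few for a share under 0.05. A larger share of dividing cells in the mutant pieces is a candidate explanation that stays open. The lower bound, 0.0999928, did not clear the 0.1 set for it, but by too little to decide anything. That interval came from resampling the 11 genes on the same arrays, so it does not measure the spread between arrays or plants.

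SPIRAL1-LIKE genes, which act on cortical microtubules, were the third, with 5 of 5 lower at a median of -0.21, and 5 of 5 also after median centring or repeated quantile normalization. None passed limma's Benjamini-Hochberg threshold (adjusted p = 0.537 to 0.827), SP1L5 and SP1L2 were as near the floor as EXPA7 and EXPA18, with wild type means of 4.23 and 4.71, and camera over 60 symbol families gave a Benjamini-Hochberg adjusted p of 0.00633, against an adjusted p of 0.823 with an estimated correlation. The median stayed at -0.18 without the array that brought it closest to 0, which argues against a single array. A shorter dissected piece may lower such genes too and stays open, since EXPA7 and EXPA18, with a median of -0.14, are too near the floor to decide. The brighter of the XTH genes and the beta-tubulin genes given above were not set as markers of length. The real split called 1 family, while 6 of the 9 other splits called more, up to 3, so that 7 of 10 splits called as many, and 10 splits cannot give a share under 0.05 in any case.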
